A study of Mus musculus with 4 samples.

How the data were processed

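Fully grown oocytes, 2-cell embryos (48 h), 8-cell embryos (68 h) and blastocysts (92 h) from F1 crosses of C57BL/6J and CBA/H mice were profiled by nanoCAGE. In this method the 5′ ends of capped RNAs are selected and sequenced from small amounts of total RNA, per the labels' protocols. Each stage is 1 sample with 2 or 3 runs, numbered 1.1, 1.2 and 2 in the oocyte, 8-cell embryo and blastocyst and 1 and 2 in the 2-cell embryo. The labels do not say whether runs came from separate pools of embryos, so they were treated as repeat runs of 1 sample. There are therefore no replicates, and no p-value, SD or SE was computed between stages.

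The table of the whole series holds read counts deposited by the authors for 47 repeat families in 11 runs, and per the file headers each column is 1 run. How often a read could be counted is not stated. The families carry the names of a repeat annotation without subfamilies, so that IAP, ETn and MERVL elements were not analysed separately here. Per the submitters' processing notes, the genome build was mm9 and CASAVA was used, with no version or role given. The aligner settings, the repeat annotation and the treatment of reads with several placements are not given in the sources used here. The read files hold 1 placement of a 25-base read per line, with chromosome, start, end, strand and a score from 1 to 99 that the authors deposited without stating its scale. The score was not used as a filter. These files name no repeat, so shares of families and classes come from the count table and positions from the read files.

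Counts were divided by the run's total over the 47 families and are given as percent, called the share. A stage's value is the mean of its runs with equal weight, and the range of its runs is given for part of the values. Families were put into 8 classes: LINE, SINE, LTR, DNA transposons, RNA genes, satellites, simple repeats with low complexity, and unclassified. The outline of these groups was fixed before the data were examined, and the class of each family was assigned from general knowledge of repeat nomenclature once the family names were seen. A family or class was said to rise or fall between stages when the stage means differed at least 2-fold and every run of one stage lay above every run of the other. If runs were independent and interchangeable between stages, chance alone would separate the runs of 20% of families with 3 against 2 runs. With 3 against 3 runs it would separate those of 10%. Repeat runs of the same sample can share a shift, which would separate the runs of more families. These rates do not allow for such shifts and are not error rates of the rule. Families given with the size of a rise or fall had at least 100 counts over both stages, and 3 LTR families with fewer are named only as members of a count, after their values were seen. They were ranked by ratio, up to 10 per direction, and the main families of each group are given besides. The planned list of subfamilies could not be used with family names.

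Exact (Clopper-Pearson) 95% intervals of shares and exact Poisson intervals of pooled ratios cover counting error only, since amplified reads without molecular identifiers are not independent molecules. Those from the count table also take each count as a different read, which the sources do not state. If reads were counted more than once, these intervals are too narrow. A count of 3 corresponds to 0.000156% of the deepest run and 0.00813% of the shallowest. Run totals ranged from 36922 to 1919263 counts. The rule was tested on runs simulated for the 47 families, 200 times per comparison. They were drawn from counts pooled over all runs, so that deep runs weighed most, with the spread within stages and each run's total. Families absent from any run were given a common spread. Deviations were drawn independently for each family and run. Families that move together, and shifts shared by runs of a stage, were therefore not simulated. With 8 families raised 4-fold the rule recovered 44.2% of them for oocyte to 2-cell, 44.4% for 2-cell to 8-cell, 35.4% for 8-cell to blastocyst and 34.0% for oocyte to blastocyst. With no change the rule called on average 6.94, 7.10, 3.22 and 4.46 families in the same order, and its 95th percentiles were 12, 13, 6 and 8.

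The first base of each read, 1-based, was taken as the read start. Starts on the same strand at most 20 bp apart over all runs were joined into clusters. For numbers of clusters and overlaps each run was thinned to the 33473 lines of the smallest run with a fixed seed. The overlap of a pair of runs is the sum over clusters of the smaller of both shares of reads, in percent. Between 1.64% and 4.34% of lines in a run repeated another line exactly and were kept. Which strand of a read corresponds to the RNA is not stated, so strands are those of the read placement. Coordinates are in mm9. The gene annotation at hand is of another build and was not used.

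Alternatives planned before the data were examined were pooled reads, transposon families only, a minimum of 100 counts, runs 1.1 and 1.2 averaged first, size factors from median ratios, each run left out, and other cluster settings. Sequencing runs were read from the read names. 3 of them hold runs of more than 1 stage: oocyte 1.1, oocyte 2 and blastocyst 1.2 share one, oocyte 1.2 and 8-cell 1.2 another, and 2-cell 2 and 8-cell 2 the third. Analyses used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.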

Results

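RNA 5′ ends within repeats were measured by nanoCAGE, a method that selects capped ends, in mouse oocytes and at 3 stages of pre-implantation development. The aim was to follow repeat transcription through early development. How far the counts come from capped ends was not tested. Each stage is 1 sample read in 2 or 3 runs, so there were no replicates, and the runs show technical or unlabelled variation only. Oocyte runs held 563012, 1919263 and 377629 counts (runs 1.1, 1.2 and 2), 2-cell runs 232146 and 245473 (runs 1 and 2), 8-cell runs 48685, 80059 and 1252133, and blastocyst runs 41528, 36922 and 93980. LINE, SINE, LTR and DNA transposon families took 37.9%, 71.1% and 72.8% of the counts of oocyte runs 1.1, 1.2 and 2. They took 91.6% and 82.2% in the 2-cell runs, 95.1%, 91.2% and 60.6% in the 8-cell runs, and 80.2%, 70.2% and 86.4% in the blastocyst runs. The share of ribosomal RNA (rRNA) ran from 0.807% in 8-cell run 1.1 to 44.9% in oocyte run 1.1.

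LTR retrotransposons were the largest class in the oocyte by mean share, at 39.9% of counts (range of runs 20.1% to 51.0%). In oocyte run 1.1 RNA genes were larger, at 45.8% against 20.1%. LTR elements took 41.0% at the 2-cell stage, 35.3% at the 8-cell stage and 24.0% in the blastocyst (19.0% to 31.0%). LINE elements, which move by an autonomous copy-and-paste mechanism, took 10.4% in the oocyte (8.88% to 11.9%), 24.7% at the 2-cell stage (16.8% to 32.6%), 24.0% at the 8-cell stage (10.9% to 34.2%) and 35.7% in the blastocyst (31.1% to 39.4%). SINE elements, short elements that depend on LINE proteins, took 9.01%, 18.6%, 20.4% and 16.7% in the same order. DNA transposons took 1.29%, 2.65%, 2.62% and 2.42%. Satellites, the tandem repeats of centromeric and pericentromeric chromatin, took 1.81%, 0.200%, 0.0994% and 1.77%, with blastocyst runs from 0.164% to 3.96%.

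**Figure D1:**
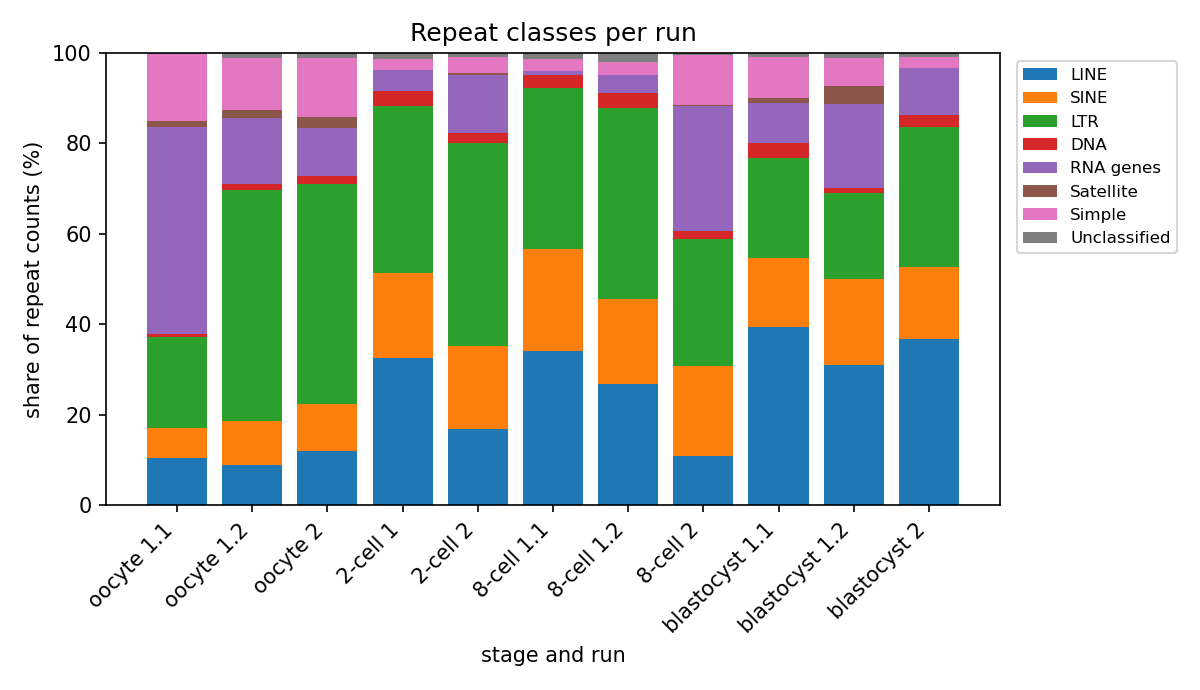
Stacked bars of the share of repeat counts (percent, vertical axis) taken by each of 8 repeat classes in each of the 11 runs (horizontal axis). LINE elements take 8.88% to 11.9% of the oocyte runs and 31.1% to 39.4% of the blastocyst runs, and RNA genes range from 0.877% in 8-cell run 1.1 to 45.8% in oocyte run 1.1.

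The comparison of oocyte and 2-cell embryo spans fertilisation and the start of embryonic transcription. ERVL elements, the family that holds MERVL and its MT2 promoters, rose from 1.44% of counts in the oocyte (0.403% to 2.30%) to 9.78% in the 2-cell embryo (5.96% and 13.6%), a ratio of 6.81. Their ratio was 5.32 among transposon families alone, 5.25 with size factors and 4.15 without 2-cell run 2, and the rule was passed each time. LINE-1 (L1) rose from 9.43% to 22.4%, a ratio of 2.38, but its ratio was 1.49 among transposon families alone, 1.35 with size factors and 1.56 without 2-cell run 1, and none of these passed. Satellites fell from 1.81% to 0.200% (9.04-fold), low-complexity sequence from 5.98% to 0.755% (7.93-fold), simple repeats from 7.06% to 2.24% (3.16-fold) and small cytoplasmic RNA from 0.424% to 0.0277% (15.3-fold). Without 2-cell run 1 the satellite fall was 5.44-fold and without 2-cell run 2 it was 26.7-fold. With size factors the falls of low-complexity sequence, simple repeats and small cytoplasmic RNA were 13.7-fold, 5.15-fold and 31.5-fold.

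The LTR families differed from each other in this step. MaLR elements (ORR1 and MT), the largest family of the oocyte by mean share, had 29.2% of oocyte counts (12.9% to 38.3%) and 16.1% of 2-cell counts (15.6% and 16.5%), with overlapping runs. In oocyte run 1.1 rRNA was larger, at 44.9%. Among transposon families alone MaLR fell from 45.9% to 18.6% (2.47-fold), with size factors it fell 2.59-fold, and it also passed without oocyte run 1.1 (2.32-fold). ERVK, the family of IAP and ETn elements, had 8.04% and 13.5% of counts, a ratio of 1.67 with all 2-cell runs above all oocyte runs and under the 2-fold limit. ERV1 had 1.27% and 1.62%. 4 of the 9 LTR families rose, and 3 of these (ERV1?, ERVL? and Gypsy?) held fewer than 100 counts over both stages.

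2 of the 6 SINE families rose, B4 from 2.60% to 6.56% (2.52-fold) and B2 from 2.57% to 5.73% (2.23-fold). B1, listed under the family name Alu, had 2.31% and 4.07%. The old L2 elements rose 3.21-fold, from 0.635% to 2.04%. Among DNA transposons with at least 100 counts, MER1_type rose 2.44-fold and Mariner 2.43-fold. Without oocyte run 1.1 their ratios were 1.80 and 1.81, and that of MER1_type was 1.91 without 2-cell run 1, which did not pass. None of B2, B4, L2, MER1_type and Mariner passed among transposon families alone, where their ratios were 1.499, 1.69, 1.87, 1.85 and 1.85, or with size factors. The small family named Genie? rose from 3 counts in all oocyte runs to 528 in the 2-cell runs, a pooled ratio of 1054 (exact 95% interval 359 to 5127). The family named Y-chromosome rose from 9 to 147 counts (pooled ratio 97.8, 50.1 to 218). The ratios of their stage means were 576 and 137 with all runs, and 349 and 80.7 without 2-cell run 1, over oocyte means of 3 and 9 counts. Leaving out oocyte run 2 for Genie? or run 1.2 for Y-chromosome left 1 oocyte count, too few for a ratio.

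In all, 15 of 47 families rose and 4 fell from oocyte to 2-cell, against an average of 6.94 and a 95th percentile of 12 called with no change in the simulation. Since the simulation drew families and runs independently, these numbers do not measure how often chance gives as many calls, here or in the other comparisons. With size factors 9 rose and 6 fell, which moved the median log2 ratio of the 38 families with at least 100 counts from 0.52 to -0.15. Among the 34 transposon families alone 7 rose and 1 fell, and of the 7 only ERVL held at least 100 counts over both stages. Of all families with at least 100 counts, 9 rose and 4 fell. No sequencing run held both stages, so that stage and sequencing run cannot be told apart in this step.

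**Figure D2:**
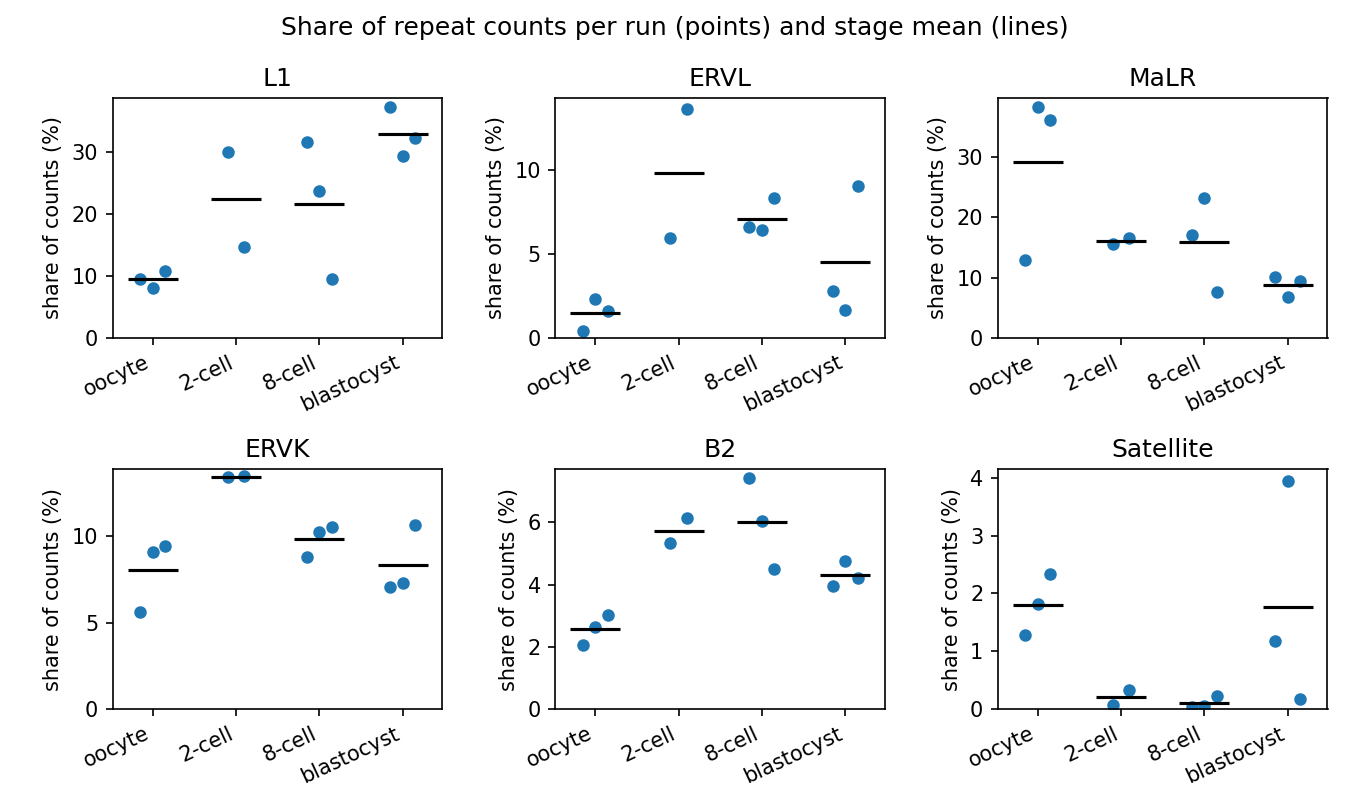
Share of repeat counts (percent, vertical axes, each starting at 0) of 6 families at the 4 stages (horizontal axes), with 1 point per run and a line at the stage mean. ERVL has its highest mean, 9.78%, at the 2-cell stage, MaLR its highest, 29.2%, in the oocyte, and L1 its highest, 33.0%, in the blastocyst.

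From the 2-cell to the 8-cell stage few families differed by the rule. L1 had 22.4% (14.7% and 30.1%) and 21.7% (9.47% to 31.7%) of counts, and MaLR 16.1% (15.6% and 16.5%) and 16.0% (7.62% to 23.3%). B2 had 5.73% and 6.00%, and B1 4.07% and 4.04%. ERVL had 9.78% and 7.08%, and ERVK 13.5% (13.4% and 13.5%) and 9.85% (8.77% to 10.5%), with all 8-cell runs below the 2-cell runs at a ratio under 2. Genie? fell from 528 counts to 53, a pooled ratio of 0.0347 (0.0257 to 0.0461). The ratio of its stage means was 0.0301 with all runs, 0.0497 without 2-cell run 1 and 0.0171 without 8-cell run 1.2. The LINE family RTE fell from 0.0625% to 0.0299%. The family named Unknown rose from 0.201% to 0.523% (2.60-fold), with a ratio of 1.91 without 2-cell run 1 and 1.96 without 8-cell run 1.2, which did not pass, and 4.07 without 2-cell run 2. RTE did not pass with size factors, without 2-cell run 1 (1.75-fold) or without 8-cell run 2 (1.64-fold).

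1 family of 47 rose and 4 fell in this step, against an average of 7.10 called with no change in the simulation. Among transposon families alone none rose and 3 fell, and of the 3 only RTE held at least 100 counts over both stages. Of all families with at least 100 counts, 1 rose and 2 fell. Without 2-cell run 2 the rule called 14 families, and without 8-cell run 1.2 or run 2 it called 8. Size factors moved the median log2 ratio of 36 families from -0.01 to 0.22. In the sequencing run that held 2-cell run 2 and 8-cell run 2, the ratio of 8-cell to 2-cell was 0.643 for L1, 0.609 for ERVL and 0.462 for MaLR, and among transposon families alone 0.872, 0.826 and 0.626. 8-cell run 2 stood apart from runs 1.1 and 1.2. It had 9.47% L1 against 31.7% and 23.8%, 26.5% rRNA against 0.807% and 3.81%, and 1.07% transfer RNA against 0.0246% and 0.0437%. Its median read score was 54, against 16 and 28, and the shares were not adjusted for the score.

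From the 8-cell stage to the blastocyst, L1 had 21.7% (9.47% to 31.7%) and 33.0% (29.4% to 37.3%) of counts, with overlapping runs. MaLR had 16.0% and 8.78%, and ERVL 7.08% and 4.48%, also with overlapping runs. Without 8-cell run 2 MaLR fell 2.30-fold, with size factors it fell 2.06-fold, and without blastocyst run 2 ERVL fell 3.20-fold. The SINE family ID fell from 0.959% to 0.434% (2.21-fold, and 3.33-fold with size factors), and Unknown fell from 0.523% to 0.125% (4.19-fold, and 7.67-fold without blastocyst run 2). Small nuclear RNA rose from 0.00964% to 0.0314% (3.26-fold, 74 and 53 counts, and 9.76-fold without 8-cell run 1.2). Satellites had 0.0994% at the 8-cell stage (0.0370% to 0.219%) and 1.18%, 3.96% and 0.164% in blastocyst runs 1.1, 1.2 and 2. Their ratio of 17.8 did not pass, whereas it passed at 44.5 without 8-cell run 2 and 25.8 without blastocyst run 2.

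4 of 47 families rose and 2 fell, with a 95th percentile of 6 calls in the simulation without change. Among transposon families alone 4 rose and none fell, and none of the 4 held 100 counts over both stages. Of all families with at least 100 counts, 1 rose and 2 fell. Without 8-cell run 1.2 the rule called 11 of the 47, and without blastocyst run 1.2 or run 2 it called 10. Size factors moved the median log2 ratio of 30 families from 0.08 to -0.57. The fall of ID did not pass without 8-cell run 2 (1.78-fold) or without blastocyst run 1.2 (1.68-fold). It also did not pass among transposon families alone, where it was 2.41-fold with overlapping runs. No sequencing run held both stages.

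Over the whole course, from oocyte to blastocyst, L1 rose from 9.43% (8.05% to 10.8%) to 33.0% (29.4% to 37.3%), a ratio of 3.50, and MaLR fell from 29.2% (12.9% to 38.3%) to 8.78% (6.71% to 10.2%), 3.32-fold. Both passed among transposon families alone, where L1 rose from 17.01% to 41.9% and MaLR fell from 45.9% to 11.1%, and both passed with size factors (2.08-fold and 4.84-fold). In the sequencing run shared by oocyte runs 1.1 and 2 and blastocyst run 1.2, the ratio of blastocyst to oocyte was 2.90 for L1 and 0.273 for MaLR. Median read scores were 50, 53 and 35 in oocyte runs 1.1, 1.2 and 2 and 16, 32 and 15 in the blastocyst runs. Shares were not adjusted for the score, so these differences between stages were not separated from it. L2 rose 3.92-fold and B4 2.29-fold. L2 and B4 did not pass among transposon families alone or with size factors. Low-complexity sequence fell 3.02-fold and small cytoplasmic RNA 3.90-fold, the former 4.63-fold without blastocyst run 1.1, while ERVK had 8.04% and 8.33%. ERVL had 1.44% and 4.48% with overlapping runs, and rose 4.47-fold without oocyte run 1.2 and 4.11-fold without blastocyst run 1.2. The DNA transposon family Tc2 rose 10.2-fold (123 and 64 counts), the family named DNA 5.797-fold (82 and 25 counts) and small nuclear RNA 6.93-fold (94 and 53 counts). Tc2 rose 16.6-fold without oocyte run 2 and small nuclear RNA 22.6-fold without oocyte run 1.1. With size factors small nuclear RNA rose 3.001-fold and the family DNA 3.76-fold, and low-complexity sequence fell 5.69-fold and small cytoplasmic RNA 7.88-fold.

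As classes, LINE rose 3.44-fold and 2.42-fold among transposon families alone. LTR had 39.9% and 24.0% of all counts with overlapping runs, and fell 2.11-fold among transposon families alone, from 63.8% to 30.2%. 13 of 47 families rose and 3 fell, against an average of 4.46 called with no change, and without blastocyst run 1.2 the rule called 27 families. Of all families with at least 100 counts over both stages, 6 rose and 3 fell. With size factors 10 rose and 5 fell, which moved the median log2 ratio of 36 families from 0.58 to -0.16.

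Across families, which are not independent replicates, log2 shares of runs of the same stage had a median Pearson correlation of 0.932 (0.890 to 0.989, 10 pairs). Runs of different stages had 0.905 (0.838 to 0.968, 45 pairs), and the median Spearman correlations were 0.931 and 0.906. By this correlation all 3 oocyte runs and all 3 blastocyst runs were closest to a run of their own stage, as were 8-cell runs 1.1 and 1.2. Both 2-cell runs were closest to an 8-cell run, and 8-cell run 2 was closest to 2-cell run 2.

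Read starts gave a view of positions that does not depend on family names. At 33473 reads per run, oocyte runs had a mean of 5205 clusters of read starts (4097 to 5991), 2-cell runs 12129 (9768 and 14490), 8-cell runs 8876 (4983 to 11457) and blastocyst runs 15582 (7820 to 24302). These numbers were not adjusted for the score of the read placements, whose median ran from 15 to 54 over runs. Blastocyst run 1.1, with the most clusters, had a median score of 16. Oocyte run 2, with the fewest, had 35, and 8-cell run 2, with 4983, had 54. Differences between stages in clusters were therefore not separated from the score. The 100 most used positions took 35.3% of oocyte reads, 26.9% of 2-cell reads, 35.5% of 8-cell reads and 30.0% of blastocyst reads (10.03% to 46.6%). Of the oocyte's clusters 5.46% had a read in another stage, against 20.9% at the 2-cell stage, 21.0% at the 8-cell stage and 7.51% in the blastocyst. Among clusters with at least 10 reads these were 27.05%, 90.3%, 76.6% and 73.9%, and without blastocyst run 1.1 the blastocyst had 13.5%. The mean overlap of runs was 20.8% between the 2-cell and 8-cell stages (7.61% to 31.0%) and 8.01% between oocyte and 2-cell (3.79% to 14.5%), and without the densest 10 kb of the genome, left out after seeing the data, 19.3% and 3.84%. Within stages it was 34.4%, 26.1%, 16.8% and 11.2% from oocyte to blastocyst. Oocyte runs 1.1 and 1.2 overlapped by 68.1% and 8-cell runs 1.1 and 1.2 by 41.0%, whereas 8-cell run 2 overlapped with runs 1.1 and 1.2 by 2.84% and 6.68%. By overlap 5 of the 11 runs were closest to a run of their own stage, against 8 by family shares.

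**Figure D3:**
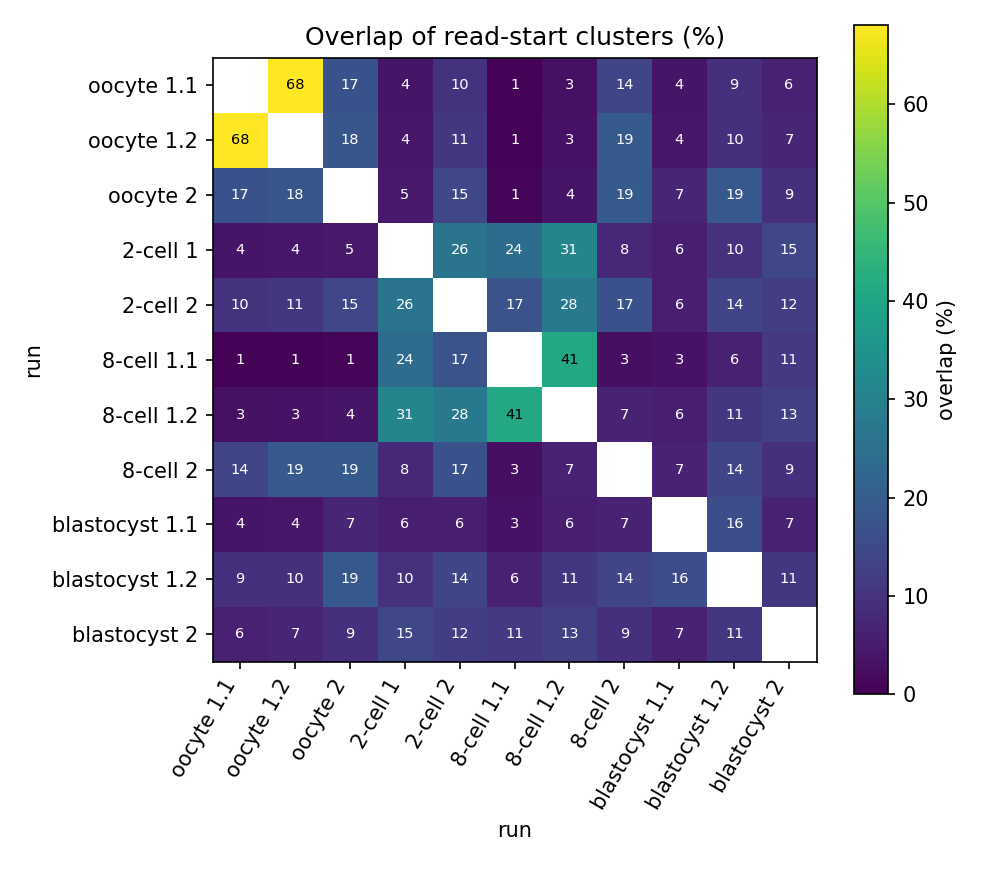
Overlap of read-start clusters (percent, colour and printed numbers) for each pair of the 11 runs (both axes), at 33473 reads per run. 2-cell runs overlap with 8-cell runs 1.1 and 1.2 by 17.4% to 31.0%, and 8-cell run 2 overlaps with all other runs by at most 19.3%.

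Clusters were ranked by reads pooled over the runs of a stage, so that the deepest run of a stage weighs most. On chromosome 17 (mm9), a cluster at 39984050 to 39985168 on the minus strand took 8.86% of oocyte reads (7.81% to 10.9%) and ranked among the first 3 at all 4 stages in this order. A neighbouring cluster at 39983301 to 39983671 took 3.61% of oocyte reads (1.43%, 1.72% and 7.69% in runs 1.1, 1.2 and 2) and 4.73% of blastocyst reads (1.32% to 9.64%). In 8-cell runs 1.1, 1.2 and 2 the larger cluster took 0.194%, 1.35% and 14.1% of reads, where rRNA had 0.807%, 3.81% and 26.5% of counts. The oocyte runs, with 10.3% to 44.9% rRNA, did not keep this order. No cluster was annotated, so whether these reads come from rRNA or from capped starts was not tested. The first 2-cell cluster lay on chromosome 8 at 106314888 to 106314898 on the plus strand. It took 3.08% and 4.63% of reads in the 2-cell runs, 1.97%, 5.20% and 0.0671% in the 8-cell runs, at most 0.00627% in the blastocyst runs, and had no read in the oocyte runs. A cluster on chromosome 11 at 86272576 to 86272587 took 3.996% and 2.06% of reads in the 2-cell runs and at most 0.0751% in the oocyte runs, 0.144%, 1.095% and 0.939% in the 8-cell runs and 0.310%, 1.06% and 0.235% in the blastocyst runs. The first blastocyst cluster by pooled reads, on chromosome 5 at 88139998 to 88140006, held 8.39% of reads in run 2, the deepest, and at most 0.00597% in runs 1.1 and 1.2. Its mean share of 2.80% was below those of both chromosome 17 clusters (4.73% and 2.81%). The third oocyte cluster lay on chromosome 1 at 124253746 to 124253800 and took 7.62% of reads in run 2 and 0.534% or less in runs 1.1 and 1.2. The third 8-cell cluster by pooled reads lay on chromosome 6 at 3151194 to 3151673 and took 1.92% of reads in run 2, the deepest, and at most 0.126% in runs 1.1 and 1.2. Its mean share of 0.697% was below that of the chromosome 8 cluster.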

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

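Shares among transposon families alone and equal numbers of reads per run were planned before the data were examined, but their use as tests of the explanations below, and all other tests in this part, were chosen after the results had been seen. Read lines on chromosome Y stood out because oocytes carry no Y chromosome and serve as the background, at 0.00991% to 0.0224% of lines. The share was 0.0329% in 2-cell run 1, 0.0376% in 8-cell run 1.2, 1.22% in 8-cell run 2, 0.0977% in blastocyst run 1.1 and 0.0669% in blastocyst run 2, each with the lower bound of its exact 95% interval above the highest oocyte run. The other 3 embryo runs did not pass this bound, with 0.0236% in 2-cell run 2, 0.0292% in 8-cell run 1.1 and 0.0149% in blastocyst run 1.2. The bound leaves out the counting error of the highest oocyte run, run 1.1, whose own interval reached 0.0288%. The lower bounds of 2-cell run 1 (0.0260%) and 8-cell run 1.2 (0.0255%) lay below that value. In 8-cell run 2, 13954 of the 14135 lines started at position 2550286 of chromosome Y, minus strand, and without them its share was 0.0157%, within the range of the oocyte runs.

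ERVL and L1 had higher shares in the 2-cell embryo than in the oocyte. More ribosomal and other non-transposon reads in the oocyte runs, the first technical explanation, would lower every transposon share there alike. Among transposon families alone the ERVL ratio was 5.32 and every 2-cell run lay above every oocyte run, which argues against it as the whole cause for ERVL. The L1 ratio was 1.49 with overlapping runs, so for L1 it stays open. The number of sequencing runs that held both stages was 0, so that a difference between sequencing runs cannot be told apart from the stage, and a change of transcription at the 2-cell stage stays open as untested.

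8-cell run 2 shared few read starts with 8-cell runs 1.1 and 1.2, which overlapped with each other by 41.0%. A difference in depth is argued against by the highest overlap of 6.68% at equal numbers of reads, and reads of the densest 10 kb of the genome, on chromosome 17, by 5.19% without that stretch. At equal numbers of reads and with the stretch kept, 8-cell run 2 overlapped most with oocyte run 2, from another sequencing run, at 19.3%, and with 2-cell run 2, from its own sequencing run, at 17.1%. Without the stretch, an alternative chosen after seeing the data, the order was reversed, at 9.83% and 11.7%, so that a shared sequencing run stays open. The labels do not say whether the runs came from different embryos, and no biological explanation was tested.

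The count table and the read files of the oocyte disagreed in size. The table total was 2.07 times the number of read lines for oocyte run 1.1 and 0.797 times for run 2, against 0.947 to 1.40 in the other 9 runs. A ratio above 1 means more counts in repeats than read lines in the whole file. Reads were then counted more than once or are missing from the read files, and the sources do not say which. With the names 1.1 and 2 exchanged the ratios became 1.19 and 1.39, inside that range, as exchanged run names in one of the sources would give. By family shares oocyte run 1.2 was closer to run 2 than to run 1.1 (Pearson correlation 0.989 and 0.923). By read starts it was closer to run 1.1 than to run 2 (overlap 68.1% and 18.1%), which also goes with an exchange. Oocyte runs 1.1 and 2 as named for shares may thus not be the libraries so named for positions. Both are oocyte runs, so stage means with equal weight for runs do not depend on it. Comparisons of shares with positions in single oocyte runs do. No biological explanation was tested.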

How the results depend on the processing

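Chosen after seeing the data were the exchange of oocyte run names, the removal of the densest 10 kb, all oocyte to blastocyst alternatives for single families and their counts (those for the other comparisons were planned, except the exchange), and size factors for classes. Counting each position once, weighting read names and taking class shares from the read files gave no value, since read lines name no family. No paired analysis was possible because there is 1 sample per stage. Of 1352 values of single families under an alternative, 1245 kept their side of the rule, 75 passed only there, 29 no longer passed and 3 turned. The 1245 include families that passed neither in the main analysis nor in the alternative. They therefore do not measure how often a called family stayed called. Counts after exchanging the oocyte run names stayed within 1.5 times. Where no cause is named, the cause was not tested. Shallow runs limit rare families.

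Among the 34 transposon families, counts of families past the rule were 8 (oocyte to 2-cell), 3 (2-cell to 8-cell) and 10 (oocyte to blastocyst) by shares of transposon counts. By shares of all counts they were 13, 3 and 12 in the same families and order. Over all 47 families 19 (oocyte to 2-cell), 5 (2-cell to 8-cell), 6 (8-cell to blastocyst) and 16 (oocyte to blastocyst) passed. Of these, families with at least 100 counts were 3 for 2-cell to 8-cell, 3 for 8-cell to blastocyst and 9 for oocyte to blastocyst. With 1 run left out, 19 to 27 of the 47 passed for oocyte to 2-cell and for oocyte to blastocyst. For 2-cell to 8-cell 6 to 14 passed and for 8-cell to blastocyst 7 to 11, since fewer runs then need to separate. Class values are log2 ratios. From oocyte to 2-cell, LINE, SINE and DNA rose by the share of all counts and did not pass among transposon families alone (0.58, 0.48 and 0.55) or with size factors (0.44, 0.39 and 0.45). SINE did not pass with pooled reads (0.99), nor SINE and DNA with run numbers averaged first (0.99 and 0.89), but both passed when oocyte run names 1.1 and 2 were exchanged before averaging (1.13 and 1.23). From oocyte to blastocyst LTR passed only among transposon families alone (-1.08), with size factors (-1.27) and without oocyte run 1.1. With 1 run left out the ranges were as follows. From oocyte to 2-cell they were 0.69 to 1.65 (LINE), 0.87 to 1.16 (SINE), 0.67 to 1.37 (DNA) and -2.36 to -0.52 (RNA genes). From 2-cell to 8-cell they were -1.86 to 1.23 (RNA genes), -2.33 to 0.56 (satellites) and -0.11 to 1.21 (simple repeats). From 8-cell to blastocyst they were -0.33 to 2.37 (RNA genes), 2.76 to 5.48 (satellites) and -0.38 to 1.07 (simple repeats). From oocyte to blastocyst they were 0.72 to 1.006 (SINE), -1.05 to -0.52 (LTR), 0.56 to 1.24 (DNA), -1.32 to -0.0081 (RNA genes), -1.43 to 0.51 (satellites) and -1.62 to -0.80 (simple repeats). RNA genes from 2-cell to 8-cell turned from 0.30 to -1.86 and fell without 8-cell run 2. Among families, rRNA turned there to -1.91 without the same run (up to 1.198 without another) and Tigger to 1.49 without 2-cell run 2 (-3.15 without run 1). The family DNA turned from oocyte to 2-cell to -2.72 without 2-cell run 1 (2.17 without run 2). With at least 100 reads per family the median correlation was 0.920 within and 0.887 between stages.

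Position values are given from oocyte to blastocyst. Identical positions gave 7996, 14564, 11160 and 17270 clusters per run. The share found in another stage was then 7.40%, 18.3%, 17.4% and 6.20%, and the overlap within stages 26.9%, 19.9%, 12.97% and 6.90%. Clusters within 100 bp gave 4891, 12074, 8821 and 15504 clusters per run. The share found in another stage was then 6.05%, 21.4%, 21.6% and 7.75%, and the overlap within stages 36.2%, 26.3%, 16.9% and 12.2%. Unthinned reads gave 32372, 42698, 27320 and 24045 clusters per run. The share found in another stage was then 4.58%, 21.8%, 22.6% and 13.6%, and the overlap within stages 36.97%, 28.9%, 17.7% and 11.3%. Clusters with at least 10 reads gave 836, 1056, 967 and 654 clusters per run. The share found in another stage was then 27.05%, 90.3%, 76.6% and 73.9%, and the overlap within stages 39.98%, 44.6%, 23.2% and 30.96%. Reads outside the densest 10 kb gave 5190, 12120, 8865 and 15574 clusters per run. The share found in another stage was then 5.35%, 20.8%, 20.99% and 7.49%, and the overlap within stages 27.7%, 24.99%, 16.3% and 7.96%. With 1 run left out, the share found in another stage ranged over 4.72% to 6.56%, 17.1% to 25.2%, 15.9% to 24.1% and 4.58% to 13.5%. The overlap within oocyte, 8-cell and blastocyst ranged over 17.1% to 68.1%, 2.84% to 40.96% and 6.87% to 16.1%, set by which pair of runs was left.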

Other observations

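Families with few counts and single runs held further differences between stages. The family named Y-chromosome had 9 counts in all oocyte runs together, 147 in the 2-cell runs, 125 in the 8-cell runs and 75 in the blastocyst runs, and its share was 0.0183% and 0.0439% in the 2-cell runs and at most 0.000417% in the oocyte runs. In 8-cell run 2 it was 0.00144%, against 0.0924% and 0.0774% in 8-cell runs 1.1 and 1.2. Genie? had 0.156% and 0.0676% of counts in the 2-cell runs and at most 0.00625% in any run of another stage. Mitochondrial reads made up 0.248% to 1.18% of lines in the oocyte runs and 1.904% in 8-cell run 2, and at most 0.550% in every other run.

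Oocyte run 1.2 and 8-cell run 1.2 were read in the same sequencing run. Between them the ratio of 8-cell to oocyte was 2.96 for L1, 2.78 for ERVL, 2.72 for B4, 0.607 for MaLR, 0.0872 for low-complexity sequence and 0.0234 for satellites. Among transposon families alone the ratios were 2.31 for L1, 2.17 for ERVL and 0.474 for MaLR. The 10 kb with the most reads lay on chromosome 17 from 39980001 to 39990000 (mm9) and held 0.418% of lines in 8-cell run 1.1 and 17.7% in 8-cell run 2, with at least 93.5% of its lines on the minus strand in every run. It was not annotated, so whether its reads are rRNA was not tested.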
